A study of Caenorhabditis elegans with 22 samples.

How the data were processed

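The data are small RNA sequencing libraries from whole wild-type (N2) hermaphrodites of Caenorhabditis elegans. Worms labelled rotenone (0.039441 µg/ml per the labels), an inhibitor of complex I of the mitochondrial electron transport chain, were set against worms labelled 2-deoxyglucose, a glucose analogue that blocks glycolysis and whose dose the labels used here do not give. Both were sampled at 1, 5, 10 and 20 days of age, with 3 libraries per group at days 1, 5 and 10 and 2 per group at day 20, which makes 22 libraries in 8 groups. The series title names a solvent control in place of 2-deoxyglucose, while the sample labels and the design text name 2-deoxyglucose, so the name used here is that of the sample labels. No untreated group was analysed here, and a difference between the groups therefore cannot be assigned to either compound. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, part of which may be technical.

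Per the labels' protocols, libraries were made with a TruSeq small RNA kit. Per the submitters' processing notes, the tools were CASAVA 1.8.4, Trimmomatic 0.36, BWA 0.7.12-r1039 and SAMtools 1.3.1-9, with no role or order stated. The reference build, the treatment of reads that map to several hairpins and the use of strand are not given in the sources used here. The authors deposited raw counts, whole numbers for each of 250 miRNA hairpins in each of the 22 libraries, and 0 columns of the table belonged to other samples. Each hairpin has a single value that sums whatever arms were counted, so the mature arms could not be separated. Reads shared by near-identical hairpins cannot be assigned: mir-44 and mir-45 held counts within 2.78% of each other in every library, and are treated as a single uncertain measurement. No other pair of hairpins with at least 100 counts in all met the tolerance of 5% in every library. Hairpins can share some reads without equal counts, so sharing in other pairs, such as mir-789-1 and mir-789-2, is not excluded. The alternative with shared hairpins removed left out mir-45 and also mir-5592-2, whose counts differed from those of mir-5592-1 by more than this tolerance in some libraries.

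Total counts per library lay between 664900 and 2233973, so 1 count was worth between 0.448 and 1.50 CPM (counts scaled to a common library total) by the raw totals. A count of 0 was read against a floor of 3 counts over the group. This floor covers counting error only, and PCR reads without molecular identifiers are not independent molecules. Pairs of libraries in a group differed far beyond counting noise in every case, with chi-square per degree of freedom from 12.1 (2-deoxyglucose day 1, libraries 2 and 3) to 327.5 (rotenone day 5, libraries 1 and 2), so no pair within a group looked like the same library deposited under different names. Libraries of different groups were not compared in this way. Library numbers within a group follow the order of the records and pair nothing.

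The counts were analysed with edgeR 4.0.16 in R 4.3.3. Hairpins were kept by filterByExpr by group (minimum count 10, minimum total count 15), which left 141; 18 of the 250 had no count in any library. Scaling factors were computed by TMM, the 8 groups were fitted in a single model with robust dispersion estimates, and contrasts were tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The median biological coefficient of variation was 13.3%. Standard errors are the log2 change divided by the square root of F. CPM values use the TMM library sizes and are given as mean ± SD. The contrasts were rotenone against 2-deoxyglucose at each age and over the mean of the 4 ages, days 5, 10 and 20 against day 1 in each perturbation, and the difference of these age changes between perturbations, for day 20 alone and for any age.

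Hairpins are named by a rule set before the data were examined. For the contrasts of perturbation at a single age and for days 5 and 10 against day 1, these are the 5 largest changes in each direction past the threshold. For the mean of the ages and for day 20 against day 1, these are the 10 largest in each direction, and for the interactions the 5 with the smallest adjusted p. A set of 15 hairpins with published roles in ageing, stress, timing or single tissues was also followed in every contrast. The text names these hairpins, and members of the lists used as examples, for some contrasts only. A hairpin of this set left unnamed for a contrast may or may not have been called there. The 10 lists, set at the same time, were the mir-35 family, which marks eggs and embryos inside the worms, the mir-51, let-7, mir-58 and mir-44 families, the mir-64 cluster, lifespan-linked and stress-linked hairpins, hairpins of differentiated tissues and mirtrons. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01, and again with an estimated correlation), with 120 tests adjusted together, and lists with fewer than 3 tested members were not tested. The share of counts held by the mir-35 family was compared by two-sided exact permutation tests.

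Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, total-count scaling, TMM computed without the mir-35 family and the 5 most abundant hairpins, no filter and a stricter filter (50 counts in 3 libraries), a fit without robust estimation, sequencing lane as a factor, a fit of only the groups compared, and each library left out in turn. Lanes came from the labels. Within an age no lane held libraries of both perturbations. No comparison of perturbations within a lane was therefore possible, and a lane term rests on the other ages. In each perturbation the day 1 libraries also shared no lane with those of day 10 or day 20. These age changes could therefore not be compared within a lane either, and a lane term for them rests on other groups. Other ways of forming the groups were counted for the contrasts of a pair of groups with at least 3 libraries each. For the mean of the ages and the any-age interaction, 100 splits within age were used, the labelled one and day 20 included.

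The procedure was tested on simulated counts for 141 hairpins with 10 hairpins changed per fold size in each of 10 simulations. For rotenone against 2-deoxyglucose at day 1 it recovered 54% of changes of 1.5-fold, 83% of 2-fold and 95% of 4-fold, with 4.53% false calls. At day 20 these were 34%, 77% and 97%, with 3.70% false calls, and for day 20 against day 1 in rotenone 41%, 83% and 100%, with 4.68% false calls. The simulated changes had random directions and covered far fewer hairpins than the 90 of 141 called between days 1 and 20 in rotenone. The rate of false calls where most hairpins change was therefore not tested. Positions come from the Ensembl release 115 annotation of WBcel235, which matched 247 of the 250 names and 140 of the 141 tested (let-7 had no match by this name), and the authors' build may differ. Permutations, annotation and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.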

Results

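Counts of 250 miRNA hairpins were compared in 22 small RNA libraries of whole wild-type hermaphrodites at days 1, 5, 10 and 20, labelled as treated with rotenone or with 2-deoxyglucose. Total counts ranged from 948172 to 2050435 at day 1, from 664900 to 2233973 at day 5, from 940056 to 1738413 at day 10 and from 850668 to 1436058 at day 20. The most abundant hairpin was mir-82, a relative of bantam, in 20 of the 22 libraries; the exceptions were the 2 rotenone libraries of day 20, led by mir-228 and mir-40. Age separated the libraries along the main axis of variation, which held 64.0% of the variance and ran from about -8 at day 1 to 10.5 or more at day 20, while the next held 11.9%. As labelled, the design followed miRNAs with age in worms given rotenone or 2-deoxyglucose.

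Between days 1 and 20 in rotenone worms, let-7, the heterochronic miRNA that times larval development, fell from 5143 ± 225 to 291 ± 30.8 CPM (n = 3 and n = 2), a log2 change of -4.14 ± 0.16 (SE). The lin-4 relative mir-237 fell further, by 4.75 ± 0.19 on the log2 scale. The paired X-linked hairpins mir-239b and mir-239a rose by 4.61 ± 0.24 and 2.68 ± 0.16, and mir-34, a relative of the p53-linked mammalian miR-34, rose by 2.78 ± 0.14. In all, 90 of 141 hairpins changed, 48 up and 42 down (edgeR quasi-likelihood F test, adjusted p for let-7 3.83e-16). Total-count scaling gave 40 up and 53 down. The other large rises were in mir-4807 (5.27), mir-2208b (5.05), mir-2208a (4.69), mir-1018 (3.39), mir-2220 (2.87), mir-8201 (2.39) and mir-36 (2.38), and the other large falls in mir-789-1 (-4.02), mir-788 (-3.76), mir-1020 (-3.70), mir-58b (-3.55), mir-789-2 (-3.38), mir-1817 (-3.27), mir-799 (-3.07) and mir-1830 (-2.67). Several of these were scarce, mir-4807 rising from 0.564 ± 0.489 to 26.1 ± 0.752 CPM, and with lane as a factor the calls of mir-2220, mir-4807, mir-228 and mir-80 were lost.

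In 2-deoxyglucose worms the same interval again lowered let-7 (-4.11 ± 0.16) and mir-237 (-4.37 ± 0.18) and raised mir-239b (4.00 ± 0.23), mir-239a (2.76 ± 0.16) and mir-34 (2.66 ± 0.14). The largest rise was that of mir-2208a, from 15.2 ± 2.84 to 1131 ± 125 CPM, or 6.17 ± 0.28 on the log2 scale. Further rises were those of mir-2220 (4.98), mir-4807 (4.93), mir-2208b (4.87), mir-1018 (4.85), mir-1832a (3.57), mir-42 (3.49), mir-43 (3.30) and mir-8201 (3.09). Further falls were those of mir-1020 (-4.51), mir-1830 (-4.37), mir-789-1 (-3.95), mir-789-2 (-3.53), mir-241 (-3.36), mir-799 (-2.99) and mir-1817 (-2.98). No count of mir-788 was left at day 20 against 148 counts over the day 1 libraries, which makes it at least 21.8-fold lower against a floor of 3 counts over the group. The test called 88 hairpins, 40 up and 48 down, and 54 up and 41 down with TMM computed without the mir-35 family and the 5 most abundant hairpins. The call of mir-4807 was lost with lane as a factor.

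**Figure D1:**
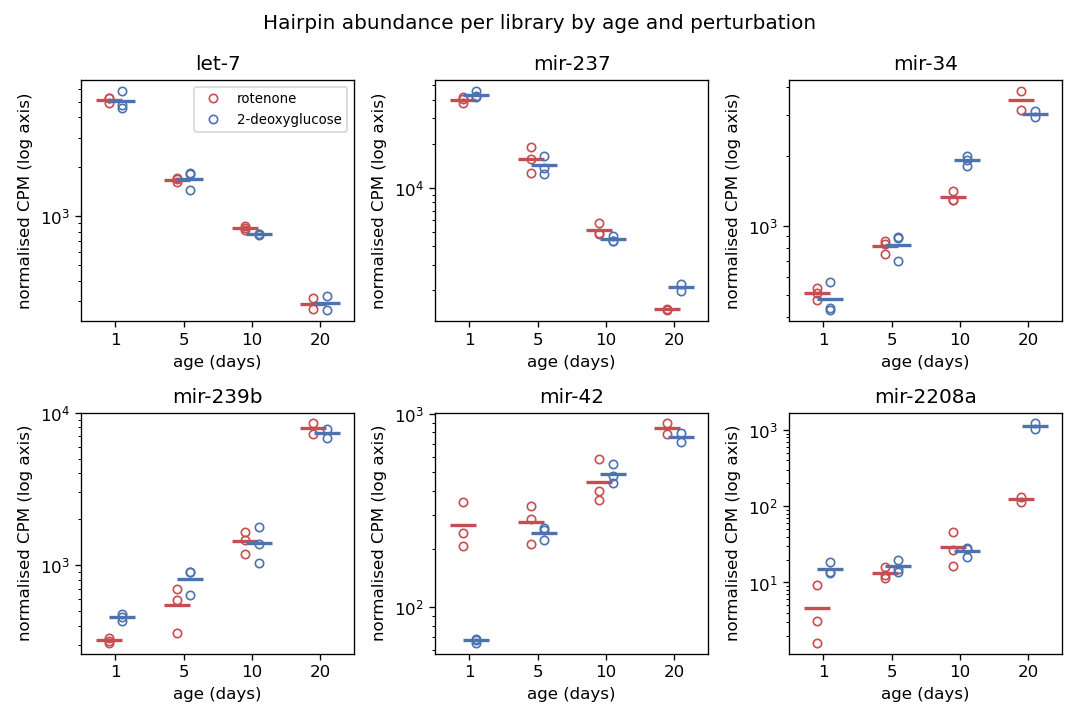
Normalised CPM (log axis) of 6 hairpins against age in days (evenly spaced categories); circles are single libraries and bars are group means, red for rotenone and blue for 2-deoxyglucose. let-7 and mir-237 fell and mir-34 and mir-239b rose with age in both perturbations, while mir-42 differed at day 1 (267 against 66.9 CPM) and mir-2208a at day 20 (124 against 1131 CPM).

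The day 20 changes of the perturbations overlapped: 39 hairpins rose in both (13.6 expected for independent lists) and 40 fell in both (14.3 expected). Past the threshold in edgeR, 0 moved in opposite directions at day 20, 2 at day 5 and 1 at day 10. Across the 141 hairpins, which are not independent replicates, the log2 changes had a Pearson correlation of 0.92 and a Spearman correlation of 0.91 (0.69 and 0.69 at day 5, and 0.77 and 0.82 at day 10). The perturbations shared no day 1 library, so these values have no common control.

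The lists behaved as follows at day 20 against day 1, with rotenone given before 2-deoxyglucose. Of the 8 mir-35 family members, 7 and 8 rose and none fell (6 and 8 with total counts); mir-36 rose by 2.38 in both, and mir-40, with a log2 change of 0.24 ± 0.18 in rotenone, was the member not called. Adjusted over the list alone the counts were again 7 and 8. Camera placed the family above other hairpins (adjusted p = 0.0160 and 0.00710), and with an estimated correlation the adjusted p = 0.43 in both. The mir-44 family, linked to sperm function, had 3 and 2 of 3 members up, though its mir-44 and mir-45 (1.38 and 1.40 in rotenone) share reads. Of the 7 let-7 family members 2 and 1 rose and 2 and 3 fell (1 up and 4 down in rotenone with total counts). let-7 and mir-241 fell in both, mir-84 rose by 1.3 and 1.09, mir-795 rose in rotenone (0.40), mir-794 fell in 2-deoxyglucose (-0.65), and mir-48, 1679 bases from mir-241, stood at -0.09 and 0.06 without passing the test. Of the 9 lifespan-linked hairpins 6 and 5 rose and 3 and 3 fell; mir-246 rose by 1.34 and 0.60 and mir-238 by 1.3 and 1.20, while lin-4 fell by 1.24 and 1.35, mir-71 by 1.05 and 1.60 and mir-80 by 0.60 and 0.63 on the log2 scale. The stress-linked list, which shares mir-34, mir-71, mir-80, mir-238, mir-239a and mir-239b with it, had 5 and 5 of 13 up and 6 and 7 down, with medians of -0.60 and -0.63 where camera pointed up without a call.

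The muscle hairpin mir-1 fell from 655 ± 52.3 to 166 ± 38.8 CPM in rotenone (log2 -1.97 ± 0.24) and by 1.69 ± 0.24 in 2-deoxyglucose, and the intestinal mir-60 fell by 1.12 ± 0.40 and 1.78 ± 0.42. The call of mir-60 in rotenone was lost without either rotenone library of day 20. The neuronal lsy-6 fell by 1.25 and 1.36, while neuronal mir-124 stood at 0.04 ± 0.47 and -0.93 ± 0.59 and mir-790 and mir-791 were not called in either perturbation. The glial mir-228 rose in rotenone (0.73 ± 0.17) and stood at 0.09 ± 0.17 in 2-deoxyglucose, a difference that the interaction test did not separate (adjusted p = 0.13). In the differentiated-tissue list 2 and 0 of 9 rose and 3 and 4 fell. The mir-64 cluster had none up and 3 of 4 down in both, the mir-58 family 1 up in both and 4 and 3 of 6 down, with mir-58a at 0.03 and 0.11, and the mir-51 family 3 and 2 of 6 up and 2 and 2 down, with a median in 2-deoxyglucose (-0.04) that was positive with DESeq2 size factors (0.08). Of 3 hairpins listed as mirtrons, mir-1018, around which the annotation used here has no protein-coding gene, rose and mir-1020 fell in both, and mir-62 rose in rotenone (0.94). None of these lists passed camera at day 20 against day 1.

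Changes were under way by day 5. In rotenone mir-1832a (2.30), mir-2208b (2.08), mir-8201 (1.88), mir-5545 (1.74) and mir-355 (1.66) rose most, and mir-799 (-1.77), mir-1817 (-1.73), mir-4813 (-1.70), let-7 (-1.63 ± 0.12) and mir-58b (-1.59) fell most. In 2-deoxyglucose the largest rises were in mir-1832a (4.20), mir-8199 (3.19), mir-8201 (3.02), mir-355 (2.27) and mir-42 (1.85), and the largest falls in mir-58b (-2.12), mir-789-2 (-2.03), mir-4936 (-1.88), mir-358 (-1.82) and mir-788 (-1.63), with let-7 at -1.58 ± 0.12. The lifespan-linked mir-238 rose by 1.24 and 1.28, mir-239a by 1.37 and 1.36, mir-71 by 0.71 and 0.43 and mir-80 by 0.71 and 0.67 in rotenone and 2-deoxyglucose. Of the 9 lifespan-linked hairpins 7 and 6 rose and 1 fell, lin-4 in both; camera gave an adjusted p = 0.0160 and 0.0228, and an estimated correlation an adjusted p = 0.43 for both. With lane as a factor the adjusted p was 0.0628 in rotenone. In all 64 hairpins changed in rotenone (35 up, 29 down; 18 and 54 with total counts) and 63 in 2-deoxyglucose (32 up, 31 down; 18 and 46 with total counts). The rise of mir-2208b was lost without rotenone libraries 1 or 2 of day 1 or 1 or 2 of day 5, among other settings.

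At day 10 against day 1, mir-34 rose by 1.39 ± 0.13 in rotenone and 1.99 ± 0.13 in 2-deoxyglucose, and let-7 fell by 2.61 ± 0.13 and 2.71 ± 0.13. Rotenone worms had their largest other rises in mir-2208a (2.63), mir-239b (2.16), mir-4807 (2.15), mir-355 (2.10) and mir-239a (2.01) and their largest other falls in mir-799 (-4.24), mir-788 (-3.47), mir-237 (-2.95) and mir-789-2 (-2.79). In 2-deoxyglucose the rises were led by mir-1832a (3.81), mir-8199 (3.06), mir-8201 (2.95), mir-42 (2.87) and mir-43 (2.66), and the falls by mir-58b (-3.53), mir-237 (-3.28), mir-788 (-3.04) and mir-799 (-2.61). Of the mir-35 family 6 of 8 members rose in rotenone and 7 in 2-deoxyglucose; camera called the latter (adjusted p = 0.00221; adjusted p = 0.43 with an estimated correlation). The lifespan-linked list was called in rotenone with 6 of 9 up and 1 down (adjusted p = 0.0160; 0.43 with an estimated correlation, and 0.0628 with lane as a factor), where mir-71 stood at 0.11 ± 0.10, and not in 2-deoxyglucose, where mir-71 fell by 0.39 ± 0.11. Counts were 78 in rotenone (41 up, 37 down; 29 and 52 with total counts; 49 and 27 with TMM without the abundant hairpins) and 93 in 2-deoxyglucose (44 up, 49 down; 36 and 62 with total counts). The call of mir-4807 in rotenone was lost in 7 of 17 alternatives, among them without any 1 of the 3 rotenone libraries of day 1.

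At day 1 the hairpins mir-42 and mir-43, whose start and end lie 5 bases apart on chromosome II (mir-42 at 11889811 to 11889905 and mir-43 at 11889910 to 11890007 in WBcel235, outside protein-coding genes), were 267 ± 75.0 against 66.9 ± 1.59 CPM and 35.6 ± 2.88 against 8.77 ± 1.51 CPM (n = 3 each), log2 differences of 1.99 ± 0.21 and 2.00 ± 0.21 (edgeR adjusted p 1.09e-07 for both). The neighbouring mir-44, at 11890023 to 11890118, was 0.50 higher, with reads it shares with mir-45. The scarce mir-8199 was 26.4 ± 4.70 against 1.32 ± 0.698 CPM (4.25 ± 0.35), mir-4813, which overlaps an exon of the isocitrate dehydrogenase gene idhg-1 on chromosome III (4571640 to 4571716), was higher by 1.27 ± 0.18, and mir-1832a, in an intron of rsp-8, by 2.53 ± 0.65. Lower in rotenone were mir-2208a (-1.71 ± 0.40), mir-241 (-0.55 ± 0.15) and mir-246 (-0.36 ± 0.11). Of the 8 mir-35 family members 4 were higher and none lower, or 7 adjusted over the list alone (camera adjusted p = 5.30e-04, and adjusted p = 0.43 with an estimated correlation). The lifespan-linked list was lower (adjusted p = 0.0407; 0.43 with an estimated correlation), with mir-246 as the member of 9 past the threshold, and the list was not called with lane as a factor (adjusted p = 0.529). The mir-44 family had 2 of 3 members higher, and none with TMM computed without the abundant hairpins.

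Among 141 hairpins 16 were called at day 1, 13 higher in rotenone and 3 lower, and 31 when the 6 day 5 libraries were left out, an alternative chosen after seeing the data. Leaving out rotenone library 1 gave 7, and 5 of the 6 omissions of a day 1 library gave fewer than 16 by over 1.5 times; the calls of mir-1832a and mir-2208a each depended on single libraries, and mir-246 lost its call whichever of the 6 was omitted. The hairpins let-7 (0.03 ± 0.12), lin-4 (-0.03 ± 0.15), mir-34 (0.08 ± 0.13), mir-1 (0.20 ± 0.19), mir-124 (0.08 ± 0.40) and mir-239a (-0.03 ± 0.14) did not pass the test, nor did mir-35 (0.45 ± 0.18), mir-71 (-0.20 ± 0.10), mir-228 (-0.36 ± 0.15) and mir-239b (-0.50 ± 0.20).

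At day 5 the hairpins higher in rotenone were led by mir-788 (1.64 ± 0.37), mir-1829b (0.95 ± 0.13), mir-36 (0.70 ± 0.15), mir-76 (0.65 ± 0.16) and mir-51 (0.63 ± 0.13), and those lower were mir-355 (-0.62 ± 0.15) and mir-87 (-0.41 ± 0.13). mir-1829b lies in an intron of F20D1.3 on chromosome X (14977119 to 14977178). The mir-35 family again had 4 of 8 members higher, or 2 with DESeq2 size factors, and 6 adjusted over the list alone (camera adjusted p = 0.0160; 0.43 with an estimated correlation). The lifespan-linked and stress-linked lists were lower by camera (adjusted p = 0.0262 for both; 0.43 for both with an estimated correlation), with no single member past the threshold. The call of mir-355 was lost without library 3 of either group. The 14 calls, 12 higher and 2 lower, became 9 and 5 with DESeq2 size factors, 11 and 4 with total counts and 8 and 4 with TMM without the abundant hairpins. The pair of libraries that differed most in the replicate check was from day 5. A fit of the 6 day 5 libraries alone called 0 (12 at unadjusted p under 0.05, and 17 by DESeq2 and 11 by limma-voom fitted to all groups), and 38 were called without the libraries numbered 1 of both groups, an alternative chosen after seeing the data.

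At day 10 mir-241 (0.67 ± 0.15), mir-83 (0.65 ± 0.19), mir-70 (0.57 ± 0.12), mir-86 (0.54 ± 0.12) and mir-65 (0.50 ± 0.15) were higher in rotenone, and mir-36 (-0.59 ± 0.15) and mir-34 (-0.52 ± 0.13) were lower. mir-34 stood at 1333 ± 65.2 CPM in rotenone and 1914 ± 91.6 in 2-deoxyglucose. The mir-35 family was lower by camera (adjusted p = 0.0160; 0.43 with an estimated correlation), with mir-36 the member past the threshold, and not with lane as a factor (adjusted p = 0.113). The call of mir-36 was lost without 4 of the 6 libraries in turn, and those of mir-34 and mir-65 without 5. The 8 calls, 6 higher and 2 lower, were 3 and 5 with DESeq2 size factors, and omitting single libraries gave between 0 and 10: without 2-deoxyglucose library 3 edgeR called 0, with 26 at unadjusted p under 0.05. DESeq2 and limma-voom, run only on all 22 libraries, called 13 and 9.

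At day 20, with 2 libraries per group, mir-2208a was the hairpin called. It held 124 ± 11.8 CPM in rotenone and 1131 ± 125 CPM in 2-deoxyglucose, a log2 difference of -3.19 ± 0.27 (adjusted p 7.57e-09), and the call was kept without each of the 4 libraries in turn and with lane as a factor. It lies on chromosome IV at 1021772 to 1021832, outside protein-coding genes, 4748 bases from mir-2208b, which held 22.4 ± 2.80 and 40.4 ± 2.50 CPM. At an unadjusted p under 0.05 there were 25 hairpins, and DESeq2 called 4 hairpins and a fit of the 4 day 20 libraries alone 18. The mir-58 family was lower by camera (adjusted p = 0.0262; 0.43 with an estimated correlation) with none of its 6 members past the threshold, and not with lane as a factor (adjusted p = 0.0628).

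Over the mean of the 4 ages the hairpins higher in rotenone were mir-8199 (1.33 ± 0.21), mir-43 (0.56 ± 0.10), mir-42 (0.55 ± 0.10), mir-74 (0.49 ± 0.10), mir-4813 (0.43 ± 0.11), mir-86 (0.35 ± 0.06), mir-38 (0.34 ± 0.09), mir-1829b (0.34 ± 0.07), mir-83 (0.33 ± 0.10) and mir-794 (0.32 ± 0.07), and mir-2208a was lower (-1.23 ± 0.17). At day 5 the differences of mir-42, mir-43 and mir-8199 were 0.20 ± 0.20, 0.03 ± 0.22 and 0.28 ± 0.28, at day 10 they were -0.14 ± 0.19, -0.26 ± 0.17 and -0.37 ± 0.32, and at day 20 they were 0.15 ± 0.23, 0.49 ± 0.18 and 1.16 ± 0.59, none past the threshold. mir-86, in an intron of Y56A3A.7 on chromosome III, stood at 912 ± 102 against 618 ± 60.5 CPM at day 5 and 965 ± 35.5 against 665 ± 35.6 at day 10. Of the mir-35 family 4 of 8 were higher and none lower (camera adjusted p = 0.0160; 0.43 with an estimated correlation). The calls numbered 15, with 14 higher and 1 lower, against 11 and 5 with DESeq2 size factors, 11 and 7 with total counts, and 24 in all with lane as a factor. Omitting single libraries gave 9 (without 2-deoxyglucose library 3 of day 1) to 17 calls, and mir-83 was lost in 28 of 34 alternatives.

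The change between days 1 and 20 differed between perturbations for 5 hairpins, listed as rotenone minus 2-deoxyglucose: mir-42 (-1.84 ± 0.31), mir-43 (-1.51 ± 0.28), mir-1018 (-1.47 ± 0.30), mir-246 (0.74 ± 0.17) and mir-241 (0.89 ± 0.25). mir-246 reached 18793 ± 1398 CPM in rotenone and 14439 ± 551 in 2-deoxyglucose at day 20, from 7422 ± 292 and 9512 ± 871. These 2 higher and 3 lower became 1 and 5 with DESeq2 size factors, and 1 and 3 with total counts or with TMM without the abundant hairpins. The call of mir-241 was lost in 15 of 22 alternatives and that of mir-246 in 8, single omissions among them, and that of mir-1018 with lane as a factor. The 5 calls were 3 without a filter, 9 by DESeq2 and 12 without the day 5 libraries, an alternative chosen after seeing the data. For let-7 (-0.04 ± 0.19), lin-4 (0.11 ± 0.25), mir-34 (0.12 ± 0.20), mir-35 (-0.17 ± 0.28) and mir-239a (-0.07 ± 0.23) no difference was detected. Taking all ages, 26 hairpins had age courses that differed, led by mir-8199, mir-2208a, mir-43, mir-42 and mir-36, and including mir-34 (adjusted p = 0.0302), mir-35 (0.0302), mir-246 (0.0150), mir-80 (0.0366) and mir-71 (0.0417), each of these 5 lost in 12 or more of 34 alternatives. Single omissions gave 11 (without rotenone library 1 of day 10) to 38 (without 2-deoxyglucose library 1 of day 5).

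The mir-35 family, the marker of eggs and embryos, held 18.1% ± 2.32 of counts in rotenone and 13.5% ± 0.973 in 2-deoxyglucose at day 1 (n = 3 each), 20.9% ± 2.88 and 14.96% ± 0.0916 at day 5, 21.1% ± 2.41 and 25.3% ± 2.33 at day 10, and 28.4% ± 2.08 and 26.1% ± 1.09 at day 20 (n = 2 each). The groups did not overlap at days 1, 5 and 10, in opposite directions at days 5 and 10, each with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows (10 tests, adjusted p = 0.143). At day 20 the exact p = 0.667, where the smallest possible is 0.333. From day 1 to day 20 the share rose by 10.3 percentage points in rotenone and 12.6 in 2-deoxyglucose (exact p = 0.1 for both, again the smallest possible). Every library of day 20 lay above every library of day 1. The 5 most abundant hairpins included 1 family member. With these 5 removed from both the family and the total, the direction of each of the 10 differences was kept.

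**Figure D2:**
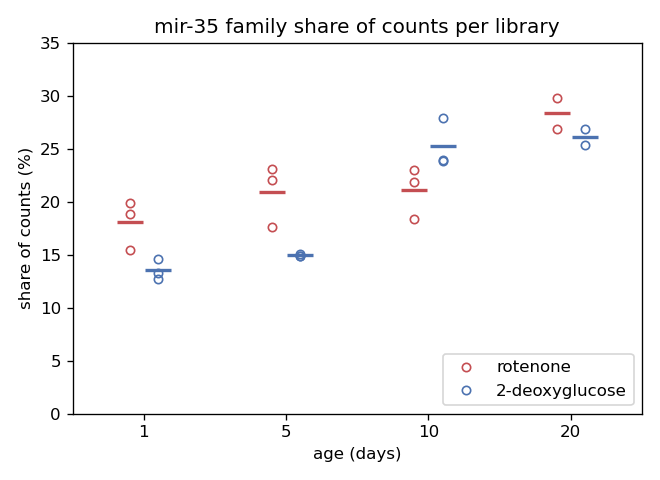
Share of all counts (%) held by the 8 mir-35 family hairpins against age in days (evenly spaced categories); circles are single libraries and bars group means. The rotenone libraries lie above the 2-deoxyglucose libraries at days 1 and 5 and below them at day 10.

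The hairpins mir-35 to mir-41 lie within 1 stretch of chromosome II, from 11537608 to 11538404 in WBcel235, inside an intron of Y62F5A.9 on the opposite strand. At day 20 against day 1 the changes along this stretch ranged from 0.24 ± 0.18 (mir-40) to 2.38 ± 0.17 (mir-36) in rotenone and from 0.50 ± 0.18 to 2.38 ± 0.17 in 2-deoxyglucose. mir-40 was by far the more abundant, with 96074 ± 17179 CPM in rotenone at day 1 against 1546 ± 138 for mir-36.

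**Figure D3:**
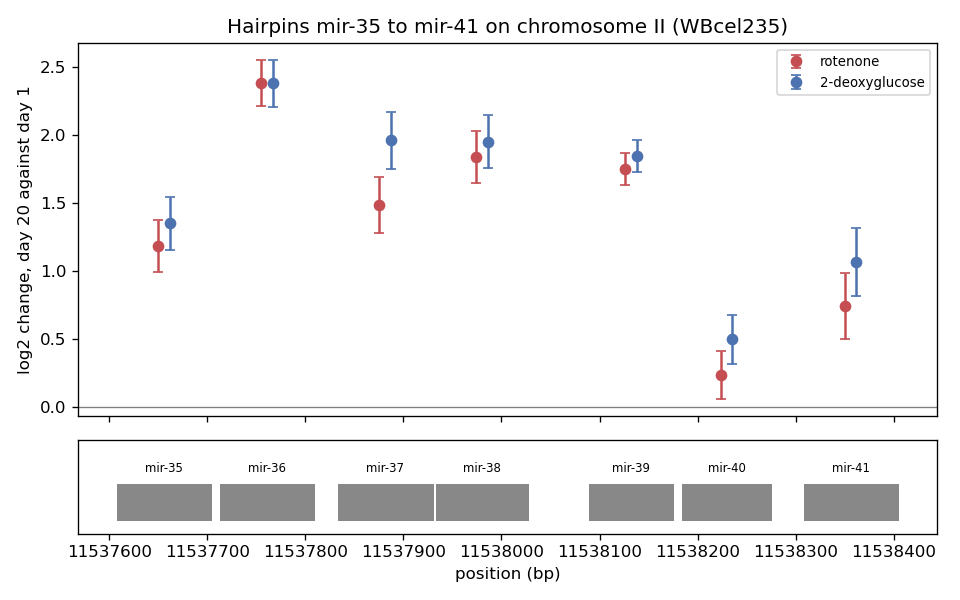
log2 change at day 20 against day 1 (points, with SE bars) of the hairpins mir-35 to mir-41 at their positions in bp on chromosome II, drawn to scale below. mir-36 to mir-39 rose by 1.49 or more in rotenone, where mir-40 stood at 0.24 without passing the test.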

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

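The tests of the mir-42 and mir-43 difference, of the rise of the mir-35 family and of exchanged labels at day 5 were chosen only after the result was seen, while the splits were set before. The lane test of day 5 was recorded as set before, but the split it concerns stood out only once the splits had been counted.

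The change between days 1 and 20 differed between perturbations for mir-42 (-1.84), mir-43 (-1.51), mir-1018 (-1.47), mir-246 (0.74) and mir-241 (0.89), by the test of the difference itself. At day 20 none of these was called between perturbations (0.15, 0.49, -0.46, 0.38 and 0.33 in the same order). At day 1 mir-42, mir-43, mir-246 and mir-241 were called. Over all ages the courses differed for mir-8199 (adjusted p = 3.08e-06), mir-2208a (7.11e-06), mir-43 (9.96e-06), mir-42 (1.99e-05) and mir-36 (7.37e-04). For mir-2208a the gap lay at day 20 (-3.19) and, smaller, at day 1 (-1.71).

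At day 1 mir-42 and mir-43 were higher in rotenone by 1.99 and 2.00. The other 7 members of the mir-35 family had a median of 0.463, so the whole family did not rise by the same factor. Whether more eggs or embryos were present could not be decided, since another source of the other members is not excluded. With lane in the model mir-42 stood at 1.92 (edgeR adjusted p = 2.15e-05). At day 1 no lane held both perturbations. The value therefore argues only against a lane effect that is the same at all ages. The counts of mir-44 and mir-45 were equal within 2.78% in all libraries, so shared reads may hide a rise of mir-44, whose sum with mir-45 was 1.40-fold higher. A difference between the perturbations stays open as a hypothesis.

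At day 20 against day 1, 7 of the 8 mir-35 family members rose in rotenone, where the abundant mir-40 stood at 0.24 (edgeR adjusted p = 0.255), and 8 rose in 2-deoxyglucose, but camera with an estimated correlation called the family in neither (adjusted p = 0.43 for both), and the rise of its share had an exact permutation p = 0.1 in both, the smallest possible (adjusted p = 0.143). With scaling that left out the family and the most abundant hairpins the lower median of both was 1.76, against scaling as the cause. The summed share rose by 10.3 points or more, that is by 4.44 and 12.9 SD of day 1. This rise argues against reads moved between members as the whole cause, but not against such moves within the family. More eggs or embryos in old worms could not be decided, since mir-36 and mir-40 moved apart by 1.88 or more and another source of the abundant members is not excluded. Age itself stays open, untested against these. The day 1 and day 20 libraries of each perturbation shared no lane, so a difference between lanes is not excluded either.

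At day 5 exchanging both libraries numbered 1 called 32 hairpins against 14 for the labels as given, which points to a structure of these samples. Each of the 2 libraries lay nearer to the other group, at 0.467 against 0.433 for rotenone and 0.476 against 0.420 for 2-deoxyglucose (mean log2 distance to libraries 2 and 3 of its own and of the other group). Exchanged labels could not be decided: the day 5 differences correlated with those of the other ages across hairpins by 0.199 as given and 0.189 exchanged, a difference of -0.0103. The mir-35 family share ran with the labels as given, at 22.1% in rotenone library 1 (23.1% and 17.7% in libraries 2 and 3) and 14.9% in 2-deoxyglucose library 1 (15.1% and 14.9%), though without the 5 most abundant hairpins 2-deoxyglucose library 1 (17.6%) lay nearer to rotenone library 3 (17.8%) than to its own group (15.4% and 15.6%). With lane in the model the exchanged split called 20 and the labelled split 12, so lane may account for part, though lane terms also cost degrees of freedom; the labels were kept as given.

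The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real split called 16 at day 1 (highest other 0; 1 split as large, the real one included), 14 at day 5 (32; 2 splits) and 8 at day 10 (0; 1 split). For age the real and highest other counts were 64 and 0 (rotenone, day 5), 78 and 0 (rotenone, day 10), 63 and 1 (2-deoxyglucose, day 5) and 93 and 0 (2-deoxyglucose, day 10). For the mean of ages, 1 of 100 splits within age was as large, the real one (15 against 9). The same held for any age (26 against 11). This argues against an arbitrary grouping of the libraries, though 100 splits allow no share below 1 in 100. Differences of culture or lane between the groups are not covered by it.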

How the results depend on the processing

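The settings without day 5 libraries and with 1 hairpin of each shared pair removed were chosen after seeing the data; all others were planned. No paired analysis was possible because the numbers of the libraries follow the order of the records and pair nothing. Adding up arms of a locus was not run, since each hairpin has a single value. Of the values of named hairpins under alternatives, 5906 kept their side of the threshold, 303 lost the call and 104 gained it. Changes of sign were counted only where the main or the alternative value was called. The test over any age has no direction, and values called in neither fit may have changed sign uncounted. The 1 change of sign counted was mir-80 at day 10 against day 1 in 2-deoxyglucose, at -0.23 with total counts. Its main value of 0.000276 (edgeR adjusted p = 0.998) had no direction to lose, and this scaling moved the median of all hairpins by as much. Lane as a factor lost 31 of 185 calls. The cause of the changes below was not tested. For rotenone against 2-deoxyglucose the counts without a filter were 9 at day 5, 4 at day 10 and 9 over the mean of ages, and 3 for the day 20 interaction. DESeq2 called 13 at day 10, 4 at day 20 and 9 for that interaction. Day 20 gave 3 with DESeq2 size factors, 4 with the stricter filter, 2 with lane and 2 with shared hairpins removed, and the mean of ages 24 with lane. Fits of only the groups compared gave 0 at day 5 (edgeR; 12 at unadjusted p under 0.05), 13 at day 10 and 18 at day 20. DESeq2 and limma-voom, run only on all groups together, called 17 and 11 at day 5. Without both day 5 libraries numbered 1 the counts were 38 at day 5, 17 at day 10, 11 at day 20, 23 over the mean, 9 for the day 20 interaction and 55 for any age. Without all day 5 libraries they were 31 at day 1, 21 at day 10, 12 at day 20, 12 for the day 20 interaction and 44 for any age. Single omissions, where a lone library is assumed to vary like the other groups, gave 7 to 11 at day 1, 10 to 26 at day 5, 0 to 10 at day 10, 9 to 17 over the mean, 3 to 6 for the day 20 interaction and 11 to 38 for any age. With an estimated correlation 0 of 120 list tests were called by camera, with 10 at unadjusted p under 0.05, against 14 with the preset. Total counts moved the median of all hairpins by -0.29, -0.18 and -0.18 at days 5, 10 and 20 in rotenone, by -0.24 and -0.23 at days 5 and 10 in 2-deoxyglucose and by -0.11 between perturbations at day 20. DESeq2 size factors moved it by -0.14 between perturbations at day 20, by 0.13 at day 20 in 2-deoxyglucose and by -0.15 in the day 20 interaction, and TMM without the abundant hairpins by 0.14 and 0.19 at days 10 and 20 in rotenone and 0.22 at day 20 in 2-deoxyglucose. With total counts at day 5 in rotenone the mir-35 family went from 3 up to 1 up and 1 down and the let-7 family from 2 up and 3 down to 5 down. Depth limits hairpins of a few counts, such as mir-4807 and mir-2208b at day 1.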

Other observations

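The test without pairs related by name or list was chosen only after the result was seen, while those of all neighbours and of hairpins inside genes were set before.

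Hairpins close together on chromosome X were higher at day 20 than at day 1: mir-4807 (1872466 to 1872526), mir-2220 (1873827 to 1873884) and mir-1018 (1879458 to 1879513, WBcel235, with no protein-coding gene at any of the 3 although mir-1018 is listed as a mirtron) rose at day 20 by 5.27, 2.87 and 3.39 in rotenone and 4.93, 4.98 and 4.85 in 2-deoxyglucose. With lane as a factor the calls of mir-2220 and mir-4807 in rotenone and of mir-4807 in 2-deoxyglucose were lost. At earlier ages mir-1018 was called at day 5 in 2-deoxyglucose (1.65) and at day 10 in both perturbations (0.88 in rotenone and 2.20 in 2-deoxyglucose), and mir-4807 at day 10 in rotenone (2.15), a call lost in 7 of 17 alternatives. At day 5 in rotenone none of the 3 was called (mir-4807 -1.13, mir-2220 -0.07, mir-1018 0.40), at day 5 in 2-deoxyglucose mir-4807 (1.20) and mir-2220 (1.96) were not, and at day 10 mir-2220 was not called in rotenone (0.49) or 2-deoxyglucose (1.93), nor mir-4807 in 2-deoxyglucose (1.18). They are named together here after their values were seen.

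Over 31 pairs of hairpins within 10 kb on the same strand, among 140 hairpins, the median difference in log2 change at day 20 was 0.594 in rotenone and 0.661 in 2-deoxyglucose, against 1.42 and 1.57 for random pairs (permutation test, one-sided, 100000 permutations, p = 0.0006 and 0.00087). Co-transcription of neighbours is a candidate explanation. Relatedness was judged by the number in the name and by the family and cluster lists, not by sequence. Over the 16 pairs unrelated by this rule the medians were 0.712 and 0.434 (one-sided permutation p = 0.0249 and 0.00051). Reads shared between neighbours related by this rule do not account for all of the similarity, while related pairs may remain among the 16. For 32 hairpins in same-strand introns of protein-coding genes no difference in median change from 108 others was detected (two-sided permutation p = 0.50 and 0.506). Hosts that rise and hosts that fall could leave the median unmoved, and host transcripts were not measured. The test therefore cannot decide on host gene transcription.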
